A study of Bos taurus with 14 samples.

How the data were processed

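Liver of 3 cattle and peripheral blood neutrophils of 4 other cattle were each sampled on day 0 and day 7 and measured on 14 single-colour (Cy3) arrays of a custom bovine design. Per the labels, total RNA was extracted with Trizol and labelled by linear amplification with a low-input kit. How the liver was sampled is not given in the sources used here.

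The spot intensities are the processed signals of Agilent Feature Extraction, version 9.5.1.1 per the file headers and 9.5 per the submitters' processing notes. Per the file headers, it subtracted the background and a spatial trend within each array and replaced low values by surrogates. The mean spot and median background intensities, used for 1 alternative, are uncorrected pixel values per the file headers. The flags for outlying, saturated and well measured spots and the grid positions are other columns of the same software, per the file headers. The log2 values of the authors' value table equal log2 of the same processed signals minus a constant per array that lies -0.013 to -0.007 from the 75th percentile (correlation 1.0, column medians -3.55 to -2.69), so their scale, centring and direction were settled from the data. A genome build is not given in the sources used here, and no coordinates are reported.

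Control spots and spots with an outlier flag (0 to 18 per array) were left out and saturated spots (0 to 3 per array) kept. The main value was log2 of the processed signal minus the array's 75th percentile, averaged over the spots of 1 probe sequence. Of 15011 probes, 6997 had exactly 1 symbol, 8 several and 8006 none. Names came from the file's accession for 2494 probes, its gene number for 2004, its symbol for 1467, a stated similarity to a human gene for 945 and the file's own name for 70, using an NCBI RefSeq gene table of the assembly ARS-UCD2.0 for names alone. For a gene with several probes, the probe with the highest mean signal in the tissue was used.

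Probes were tested when well above background on every array of at least 1 of the days in that tissue (10933 in liver, 9450 in neutrophils, 8841 for the difference between tissues). Day 7 was compared with day 0 by limma 3.58.1 (R 4.3.3; lmFit and eBayes) with the animal as a block, within each tissue, and the difference between tissues in 1 model over all arrays. P-values are two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05 on the adjusted value. Errors of log2 changes are the standard errors of these fits, moderated over all probes by eBayes. The fits hold 3 animals in liver and 4 in neutrophils, and for the difference between tissues all arrays. These errors are not the spread between animals, and can be smaller or larger than it. Pairing comes from the labels, which name the same animal on both days. The correlation of the paired deviations from the group means was 0.65, 0.31 and 0.61 in liver animals 58, 61 and 66 and 0.61, 0.36, 0.03 and 0.24 in neutrophil animals 25, 26, 32 and 34.

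A probe not well above background on any array of 1 day has only a bound there. Its fold is given as at least the mean of the brighter day over a dim-day mean, where each array enters with the higher of its lowest signal among probes well above background and the probe's own signal. No fold is given where this falls under 1.

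A set of 42 gene lists (28 pathway lists and 14 lists of cell type markers) was tested with limma's camera at a preset correlation of 0.01, for lists with at least 5 measured genes, which gave 35 lists in liver, 25 in neutrophils and 19 for the difference. None of the calls held with an estimated correlation. That form of the test rests on the few residual degrees of freedom of each fit, so an adjusted p under 0.05 is hard to reach. A miss there therefore decides little. Before adjustment its smallest p was 0.023 in liver (muscle and adipose list) and 0.0764 in neutrophils (proliferation list). Fry, which asks whether a list's genes move on balance one way without comparing them with other genes, gave adjusted p from 0.0645 in liver and from 0.49 in neutrophils. The designs, gene lists, named-gene rule and most alternatives were fixed before the data were examined. Per tissue and direction the rule takes the 10 genes with the largest change among those past the threshold that moved the same way in every animal, filled by smallest p where fewer qualify, 5 per direction for the difference between tissues, and up to 4 members of each list. Others, such as RPL7, VNN1, LTF and HSP90AB1, come from that list rule where they led a list.

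The alternatives were no block, normexp background correction (offset 50) with quantile normalization, quantile normalization of the processed signal, the authors' values, other filters on dim probes, each animal left out, 1 fit over all arrays, other thresholds (adjusted p of 0.1, or unadjusted p of 0.05 with 1.5-fold), array weights, an estimated correlation, fry and the mean over probes. After the data were seen, removal of a loess trend (span 0.12) along the spot rows of each array and use of the inner rows without the first and last 40 were added.

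The procedure was tested on simulated data with independent noise for each probe. The recovery runs held no trend along the spot rows, so their false calls do not cover such a trend. In the liver design 90 of 100 probes changed by log2 1 and 99 of 100 changed by 2 were recovered, with 18 false calls. In the neutrophil design the numbers were 7 and 87 of 100 with 6 false calls, and for the difference between tissues 3 and 74 of 100 with 6 false calls. Further runs held a row trend of a chosen size, not fitted to these arrays, and no change. They gave 3023 false calls in liver and 890 in neutrophils, and 0 in each with the trend removed. The simulated trend was smooth and alike for every probe of a row. On the liver arrays, changes in the first 16 rows kept an SD of 0.75 after the removal, against 0.32 in rows 41 to 152. The 0 false calls do not cover what is left in the edge rows. The number of arrays limits the precision, and with tissue on its own slide and day on its own slide row neither can be told apart from position.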

Results

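Gene expression in liver and in peripheral blood neutrophils of Holstein cattle (Bos taurus) was compared between day 0 and day 7 of a supplementation with β-cryptoxanthin, a carotenoid pigment that animals can cleave to vitamin A. The animals, heifers or steers, received 0.2 mg of β-cryptoxanthin per kg body weight by mouth on day 0. Liver came from 3 cattle (animals 58, 61 and 66) and neutrophils from 4 other cattle (animals 25, 26, 32 and 34), each sampled on both days, which gave 14 arrays in 4 groups. No untreated animals were analysed here, so each comparison is between days within the same treated animals. An effect of the carotenoid cannot be told apart from any other effect of the 7 days. The study's title places the transcripts beside the functions of blood leukocytes, and the comparisons ask which transcripts differed after 7 days in each tissue and whether that difference was alike in both.

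Each array carried 15208 spots that were not controls, for 15011 distinct probes, of which 6997 could be assigned exactly 1 gene symbol. In liver, 74.7 to 76.7% of the spots were well above background on day 0 and 62.7 to 75.1% on day 7. In neutrophils the range was 63.5 to 71.6% on day 0 and 57.1 to 69.0% on day 7. The day 7 neutrophil array of animal 34 was the weakest, with a median processed signal of 48.2 against 100.2 to 162.9 in the other day 7 neutrophil arrays, and its correlation across probes with the other neutrophil arrays lay between 0.86 and 0.92. All liver arrays lay on slide 1 and all neutrophil arrays on slide 2, and on each slide day 0 filled the first row of arrays and day 7 the second. The day therefore cannot be told apart from the position on the slide. The number of arrays limits the precision of every comparison below.

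The largest differences in liver were in transcripts of skeletal muscle, which were near or below the detection limit on day 0 and readily measured on day 7 in all 3 animals. TNNC2, the calcium-binding troponin C of fast muscle fibres, was at least 49.99-fold higher on day 7 (log2 change 7.94 ± 0.45, SE, adjusted p = 0.00787). MYL1, a myosin light chain of fast fibres, was at least 62.39-fold higher (7.24 ± 0.42, adjusted p = 0.00787). CKM, the muscle creatine kinase, was at least 16.63-fold higher (6.35 ± 0.37, adjusted p = 0.00817), and MB, the oxygen-binding protein myoglobin, at least 32.44-fold higher (6.33 ± 0.26, adjusted p = 0.00692). These 4 transcripts were not well above background on any day 0 array, so each fold is a lower bound. ACTA1, the skeletal muscle actin, rose by 7.85 ± 0.52 on the log2 scale (adjusted p = 0.01; well above background on 2 of the 3 day 0 arrays). The increase was 7.04 ± 0.55 for TNNC1, the troponin C of slow fibres, (adjusted p = 0.0124; 1 of 3). It was 4.72 ± 0.29 for TNNT3, the troponin T of fast fibres (adjusted p = 0.00935; 1 of 3), and 5.16 ± 0.52 for MYH7, the slow myosin heavy chain (adjusted p = 0.0186; 3 of 3). On the list of muscle and adipose tissue markers, 6 of 11 measured members rose over all probes tested and 7 when adjusted over the list alone. All 6 code for skeletal muscle proteins (MB, MYL1, CKM, TNNT3, ACTA1 and MYH1). The median change of the list was 4.62, or 2.78 with the 4 members without a day 0 level at their bounds (limma camera, adjusted p = 2.49e-08). With an estimated correlation camera gave an adjusted p of 0.759 and an unadjusted p of 0.023. The other 5 members did not pass, among them the smooth muscle or mesenchymal markers MYLK (0.46, adjusted p = 0.178), DES (0.41, 0.491) and CNN1 (0.10, 0.982), and the adipocyte markers CIDEC (0.59, 0.471) and FABP4 (adjusted p = 0.448). With normexp background correction and quantile normalization the changes were smaller, for example 3.46 for TNNC2 and 2.10 for CKM, both past the threshold, and the median of the list was 1.32. Without the filter on dim probes the list held 14 members with a median of 1.47 (adjusted p = 2.45e-07), and the 8 genes above had the same changes and did not pass (adjusted p between 0.095 and 0.129), nor did they without animal 58 (4.31 to 7.98, adjusted p between 0.0946 and 0.121).

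**Figure D1:**
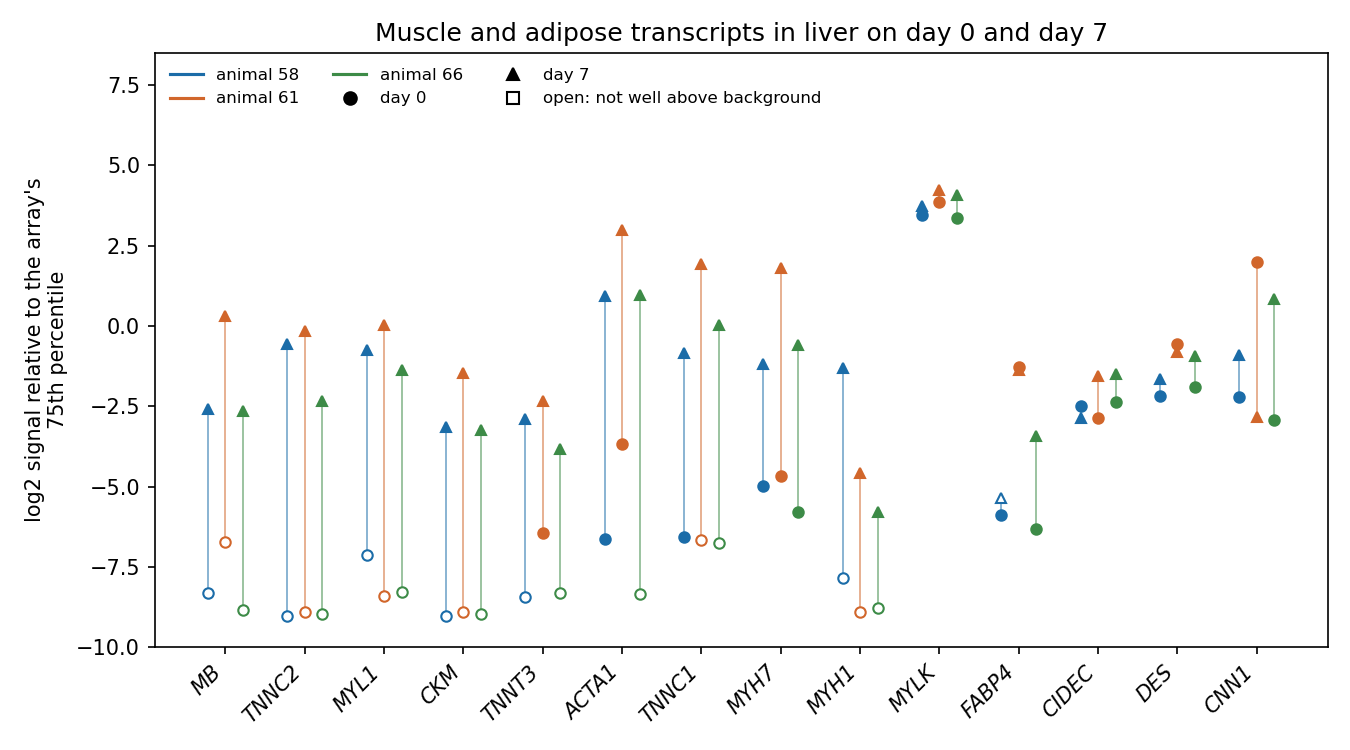
Log2 signal relative to the array's 75th percentile (vertical axis) of the 11 members of the muscle and adipose list and of TNNC2, TNNC1 and MYH7 (horizontal axis) on the 6 liver arrays, circles for day 0 and triangles for day 7, 1 colour per animal, with open symbols where the spot was not well above background. The skeletal muscle transcripts from MB to MYH1 were higher on day 7 in all 3 animals, whereas MYLK, FABP4, CIDEC, DES and CNN1 did not pass the test.

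Genes of cholesterol synthesis and uptake were higher in liver on day 7, with a positive change in 14 of 14 measured members and a median change of 0.76 (0.48, 0.76 and 1.01 in animals 58, 61 and 66; camera, adjusted p = 1.39e-07; adjusted p = 0.759 with an estimated correlation). Of the 14 members, 3 passed over all probes tested and 9 when adjusted over the list alone. NSDHL, a sterol dehydrogenase, rose by 1.49 ± 0.17 (adjusted p = 0.0242), HMGCS1, the cytosolic HMG-CoA synthase, by 1.05 ± 0.15 (0.0379) and DHCR7, the enzyme of the last step to cholesterol, by 1.06 ± 0.16 (0.0431). FDPS, farnesyl diphosphate synthase, had 1.25 ± 0.21 and did not pass (0.0549). In spot rows 41 to 152 alone, 6 members of the list had a median of 0.46 (adjusted p = 8.74e-05). Proliferation genes were lower, with a median of -0.69 over 19 members (-0.61 with 2 members at their bounds; adjusted p = 0.000329; adjusted p = 0.759 with an estimated correlation). CCNB1 (-1.36 ± 0.19, adjusted p = 0.0403) and CDK1 (-1.27 ± 0.19, adjusted p = 0.0416), the cyclin and kinase that drive entry into mitosis, fell, and 4 members fell when adjusted over the list alone. With the trend along the spot rows described below removed, none of the 5 called genes of these lists passed, with changes about as large: NSDHL 1.36, HMGCS1 1.09, DHCR7 1.02, CCNB1 -1.33 and CDK1 -1.29 (adjusted p = 0.092, 0.119, 0.138, 0.129 and 0.122). CCNB1 was well above background on 2 and CDK1 on 1 of the 3 day 7 arrays. The median change of the proliferation list was -0.11 in animal 58 against -0.84 and -0.86 in animals 61 and 66. Restricted to probes well above background on every liver array, that list no longer passed (median -0.16, adjusted p = 0.349). Its median was -0.21 with normexp and quantile normalization (adjusted p = 0.0109), where CCNB1 (-0.58, 0.0932), CDK1 (-0.43, 0.102) and, of the cholesterol list, NSDHL (1.11, 0.0635) did not pass, and -0.18 over 12 members in rows 41 to 152 (0.0118).

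Smaller shifts passed for 4 further lists in liver, each with an adjusted p of 0.759 with an estimated correlation. The median change was 0.12 over 70 oxidative phosphorylation genes (adjusted p = 7.42e-05), 0.23 over 21 hepatocyte markers (0.000129), 0.18 over 18 genes of xenobiotic metabolism (0.0493) and -0.14 over 31 genes of Toll-like receptor and NF-kB signalling (0.0407). Of the oxidative phosphorylation genes, 3 rose (COX7C, 2.22; NDUFS8, 1.19; NDUFS6, 1.04) and 1 fell (SDHD, -1.74), and these lie in spot rows 3, 9, 7 and 190 of the 192 rows of the array. Among hepatocyte markers RBP4, the plasma carrier of retinol (0.86, adjusted p = 0.0271), FGB, the fibrinogen beta chain (1.05, 0.0325) and AMBP (1.47, 0.0331; measured in both days of 2 animals after outlier spots were left out) rose, and in xenobiotic metabolism CYP2D14 rose (1.42, 0.0107). CYP2D14 and AMBP lie in rows 4 and 7, and with the row trend removed CYP2D14 had 0.34 (adjusted p = 0.294), AMBP 0.74 (0.239) and FGB, in row 19, 0.83 (0.158). NDUFS8, NDUFS6 and SDHD then had 0.61, 0.30 and -0.99 and, like COX7C (adjusted p = 0.152), did not pass. No member of the Toll-like receptor list passed. These 4 shifts were lost with quantile normalization of the processed signal, where the medians were 0.04, 0.07, 0.05 and -0.15 (adjusted p = 0.108, 0.223, 0.372 and 0.118), and with normexp and quantile (adjusted p = 0.0777, 0.176, 0.331 and 0.156). The xenobiotic list also missed the threshold without the animal as a block (0.0587), without the filter on dim probes (0.0787), without animal 58 (0.061) and without animal 61 (0.223), and the Toll-like receptor list without animal 61 (0.0816) and without animal 66 (0.0573) and with the row trend removed (0.0631). Neither of these lists passed with probes well above background on every array (0.101 for each) or in rows 41 to 152 (0.0508 and 0.45).

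The list most closely tied to the treatment, retinoid and carotenoid handling, did not shift in liver (22 genes, median 0.06, adjusted p = 0.446). RBP4 rose as given above, TGM2, a retinoic acid-inducible transglutaminase, fell (-1.12 ± 0.14, adjusted p = 0.0304), and RARG, a retinoic acid receptor, fell (-0.93 ± 0.14, adjusted p = 0.0421). When adjusted over the list alone, 4 members were higher and 2 lower. RXRA, the common partner of the nuclear retinoid receptors, had 1.51 ± 0.25 and did not pass (adjusted p = 0.0521), and its other probe had -0.22 (adjusted p = 0.602). The probes lie in spot rows 25 (RBP4), 189 (TGM2), 75 (RARG), 8 and 100 (RXRA). None of them passed once the trend along the spot rows described next was removed. RARG (-0.94, adjusted p = 0.113) and RBP4 (0.71, 0.114) then had changes near those above, whereas TGM2 had -0.48 (0.306) and RXRA 0.86 (0.319; -0.22 and 0.665 for its other probe).

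Over all 10933 probes tested in liver, 292 were higher and 143 lower on day 7 (limma with the animal as a block, adjusted p under 0.05; 210 probes without the block), and 141 of the higher and 66 of the lower probes carried 1 gene symbol. The calls were unevenly placed on the array. The first 16 spot rows held 7.47% of the probes tested, 225 of the higher calls and no lower call. The last 16 rows held 8.15% of the probes, 3 of the higher and 123 of the lower calls. These rows together held 80.7% of all calls. The median change over all probes was 0.54 in the first 16 rows (0.47 to 0.61 in the 3 animals), -0.04 in rows 41 to 152 and -0.38 in the last 16 rows. In neutrophils the corresponding medians lay between -0.05 and -0.09 throughout. GAPDH, a glycolytic enzyme gene printed as 1 sequence in 100 spots, changed more in the first 40 than in the last 40 rows by 0.88, 0.96 and 1.01 in the 3 livers and by 0.08 to 0.13 in the 4 neutrophil samples. With the row trend of each array removed, 18 higher and 4 lower probes passed, all 22 among the 435. Of the 435 calls, 55 had the opposite sign with the trend removed, among them a single-spot GAPDH probe in row 1 (1.13 before, -0.41 after) and ENG, the endothelial coreceptor endoglin, in row 3 (0.88 and -0.34). With rows 41 to 152 alone, 0 of 6475 probes passed, although the changes there are those of the full fit (ACTA1 7.85, MYL1 7.24, TNNC1 7.04 and TNNT3 4.72, adjusted p between 0.091 and 0.121). Probes at an unadjusted p under 0.05 numbered 1951 in the full fit, 1342 with the trend removed and 628 in the inner rows, which raises the adjusted p of a gene whose change is the same. Leaving out animal 58, 61 or 66 left 0, 116 or 159 calls.

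**Figure D2:**
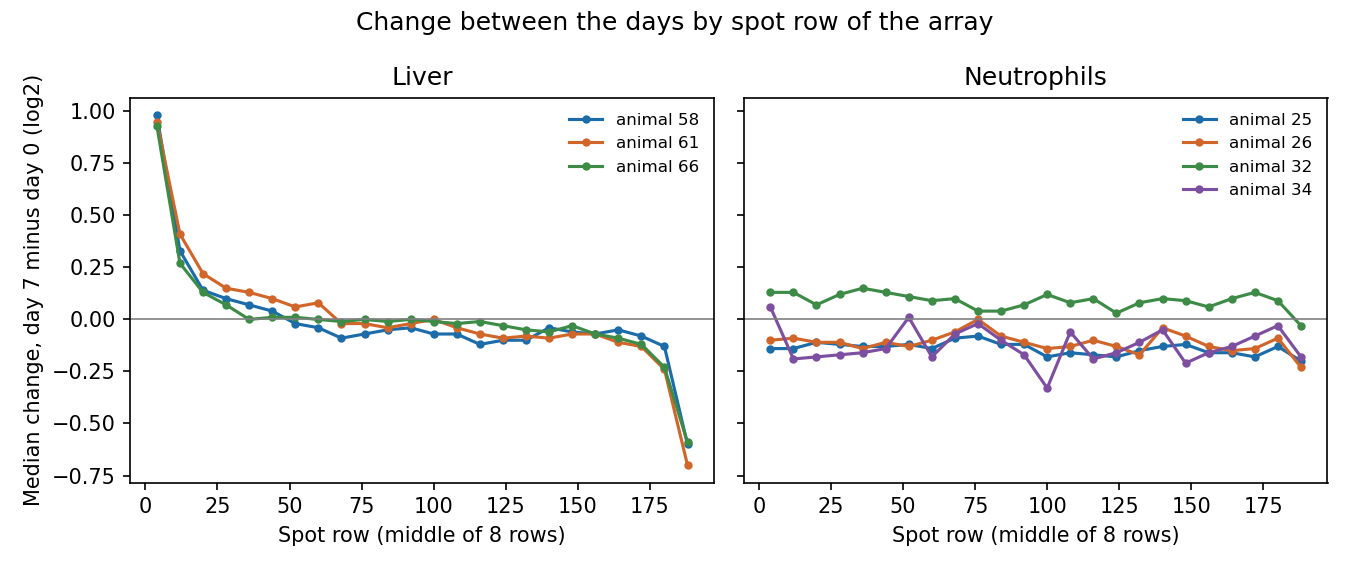
Median change from day 0 to day 7 (vertical axis, log2) of the tested probes in successive groups of 8 spot rows (horizontal axis, middle row of the 192), 1 line per animal, in liver (left) and neutrophils (right). In liver all 3 animals run from 0.93 to 0.98 in the first 8 rows to between -0.59 and -0.70 in the last 8, and the 4 neutrophil samples show no such slope.

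The 10 genes named for an increase in liver, ranked by fitted change, were the 8 muscle genes above together with LAS1L, a ribosome biogenesis factor (5.78 ± 0.30, adjusted p = 0.00696; well above background on 1 of 3 day 0 arrays), and MSX2, a homeobox transcription factor (5.04 ± 0.16, adjusted p = 0.00689), which lie in spot rows 2 and 1. With the row trend removed, LAS1L changed by 4.40 (adjusted p = 0.0335) and MSX2 by 3.51 (0.0177). The removal takes out only a smooth curve through the row medians. Liver changes still spread more in the first and last 16 rows afterwards (SD 0.75 and 0.58) than in rows 41 to 152 (0.32). Passing after the removal therefore does not clear a gene in the edge rows of an effect of its position. The muscle genes lie in rows 39 to 192. With the row trend removed, TNNT3 changed by 4.71, TNNC1 by 7.06 and ACTA1 by 7.82, and MYH7 had 5.20 and did not pass (adjusted p = 0.078). Those without a day 0 level were higher by at least 4.14 for CKM, 5.96 for MYL1 and 6 for MB on the log2 scale, and TNNC2 also passed (adjusted p between 0.0177 and 0.0486 for all but MYH7). With normexp and quantile normalization the changes of LAS1L (2.39), MARS1 (-1.95), LHX2 (-1.25) and CANX (-1.40) were smaller and passed. The 10 genes named for a decrease, also ranked by fitted change, lie in rows 190 to 192. They were MARS1, the methionyl-tRNA synthetase (-4.52 ± 0.46, adjusted p = 0.0186), and HES1, a Notch target (-4.02 ± 0.35, 0.0157), followed by MAFG (at least 8.54-fold lower, 0.0107), PALLD (at least 2.26-fold lower, 0.0421), LHX2 (-2.84 ± 0.16, 0.00787), SLMAP (-2.63, 0.00692), SDC2 (-2.21, 0.00696), CANX (-2.16, 0.0118), VPS54 (-2.10, 0.0107) and MKNK1 (-2.07, 0.0186). MAFG and PALLD were not well above background on any day 7 array, and MARS1 and LHX2 were on only 1 of 3. At their bounds CKM (4.06) lies below GBF1 (4.53) and PALLD (-1.18) is smaller than SDHD (-1.74), so their places among the 10 are not established. With the row trend removed, 1 of these 10 passed, LHX2 (-1.98, adjusted p = 0.0335). The others kept smaller changes as fitted, from -3.77 for MARS1 and -3.04 for HES1 to -1.09 for MKNK1, with adjusted p between 0.0514 and 0.214. All 20 genes moved the same way in all 3 animals, which the naming rule required.

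The other 28 lists tested in liver did not pass (adjusted p between 0.0733 and 0.868). Medians were 0.08 for antioxidant and glutathione enzymes, 0.15 for acute-phase proteins, -0.16 for interferon-stimulated genes, 0.05 for fatty acid oxidation and PPARA targets and 0.14 for lipogenesis. Markers of other liver cells had medians of -0.11 for Kupffer cells, -0.24 for endothelium, -0.18 for stellate cells and fibroblasts and -0.37 for cholangiocytes. With members at their bounds the endothelial median was -0.20. The neutrophil markers in liver had a median of -0.28 (-0.13 with 1 member at its bound), and LTF, the granule protein lactoferrin, had -2.11 ± 0.48 without passing (adjusted p = 0.109). Of the acute-phase genes, HP, haptoglobin, had -1.44 ± 0.27 (adjusted p = 0.0754). VNN1, a pantetheinase and PPARA target, rose by 2.40 ± 0.10 (adjusted p = 0.00692) in spot row 3, and had 1.18 with the row trend removed (adjusted p = 0.0514). Of the 28 lists, 7 passed with the row trend removed, with medians of 0.06 for ribosomal proteins (adjusted p = 0.00377), 0.09 for proteasome subunits (0.0272), 0.06 for antioxidant enzymes (0.0105), 0.10 for acute-phase proteins (0.0105) and 0.14 for the growth hormone and IGF axis (0.0208). The medians were -0.16 for interferon-stimulated genes (0.0149) and -0.28 for extracellular matrix genes (0.0439, and -0.24 before), and with an estimated correlation each of the 7 had an adjusted p of 0.663. In rows 41 to 152, 6 of the 28 passed: ribosomal proteins (0.08, adjusted p = 0.00151), proteasome subunits (0.08, 0.044), interferon-stimulated genes (-0.20, 0.00524), extracellular matrix (-0.25, 0.0429), lipogenesis (0.22, 0.0118) and fatty acid oxidation (0.11, 0.0323), each with 0.651 with an estimated correlation. Extracellular matrix genes also passed without the filter on dim probes (-0.23, 0.0393), without animal 58 (-0.42, 0.0276) and without animal 66 (-0.38, 0.0219). Ribosomal proteins (0.09, 0.0344) and proteasome subunits (0.16, 0.00872) passed without animal 58, interferon-stimulated genes (-0.26, 0.0444) without animal 61, and antioxidant enzymes (0.15, 0.0365), glycolysis and gluconeogenesis (0.15, 0.00778) and cholangiocyte markers (-0.75, 0.0365) without animal 66. With an estimated correlation these calls had an adjusted p of 0.696 or more.

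In neutrophils, ribosomal protein genes and proliferation genes were higher on day 7 and genes of adhesion and migration were lower as groups, while no single gene passed. The 61 cytosolic ribosomal protein genes had a median change of 0.56 (camera, adjusted p = 1.62e-11), with positive fitted changes in all 61. With an estimated correlation the adjusted p was 0.777 for this list and for the next 2. Examples, none past the threshold, were RPL7 (1.14 ± 0.33, adjusted p = 0.313) and RPLP2 (0.89 ± 0.28, 0.314). The medians per animal were 0.45, 0.90 and 1.13 in animals 25, 26 and 34 and -0.04 in animal 32. The 17 proliferation genes, 12 with a positive and 5 with a negative change, had a median of 1.08 (adjusted p = 0.000122, and 0.777 with an estimated correlation), with 0.83, 1.33, 0.68 and 0.55 in animals 25, 26, 32 and 34. Adjusted over the list alone, 9 of the 17 were higher, among them CCNA2 (1.08 ± 0.24), RRM2, a subunit of ribonucleotide reductase (1.66 ± 0.37), CDK1 (1.64 ± 0.38) and CCNB1 (1.49 ± 0.35), each with an adjusted p of 0.301 over all probes. The 29 genes of adhesion, chemotaxis and migration had a median of -0.49 (adjusted p = 0.0004, and 0.777 with an estimated correlation), with -0.52, -0.29 and -0.94 in animals 25, 26 and 34 and 0.28 in animal 32. Adjusted over the list alone, 2 of them were lower, ALOX5, the first enzyme of leukotriene synthesis (-2.36 ± 0.49), and CCR3, an eosinophil chemokine receptor (-1.56 ± 0.33). ITGAM, the integrin alpha M of the complement receptor on myeloid cells, had -1.24 ± 0.32 (adjusted p = 0.306). Without animal 34 the median was -0.18 for adhesion (adjusted p = 0.00289), 0.43 for ribosomal proteins and 0.95 for proliferation. With normexp and quantile normalization it was 0.59 for proliferation and -0.30 for adhesion (adjusted p = 0.000116 for each).

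Markers of lymphocytes in the neutrophil samples had positive medians that did not pass, 0.39 over 9 T cell markers (adjusted p = 0.0895), 0.74 over 7 B and plasma cell markers (0.0895) and 0.32 over 7 NK and cytotoxic cell markers (0.0923), against -0.03 over 18 neutrophil markers (0.996). JCHAIN, the joining chain of secreted immunoglobulins, had 1.56 ± 0.28, GZMB, a protease of cytotoxic lymphocytes, 1.31 ± 0.27 and CD3G, a chain of the T cell receptor complex, 1.05 ± 0.25 (adjusted p = 0.301, 0.301 and 0.302), each positive in 4 of 4 animals. Without animal 34, whose T cell median was -0.57, the T cell list (0.78, adjusted p = 4.02e-05) and the B and plasma cell list (0.70, 0.00234) passed, as did the interferon-stimulated genes (0.67, 0.00289) and the monocyte and macrophage markers (0.49, 0.0408). The T cell and B cell lists also passed with normexp and quantile normalization (0.35, adjusted p = 0.0148, and 0.36, 0.028) and with probes well above background on every array (0.49, 0.0268, and 0.87, 0.0192). The B cell list passed in rows 41 to 152 (5 genes, adjusted p = 0.0184) and the NK list without animal 32 (0.60, 0.0468). With an estimated correlation the adjusted p of each of these calls was 0.548 or more. The T cell, B cell and ribosomal medians were all positive in animals 25 and 26. In animal 32 the T and B cell medians were 0.57 and 0.93 with a ribosomal median of -0.04, and in animal 34 they were -0.57 and -0.07 with a ribosomal median of 1.13.

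**Figure D3:**
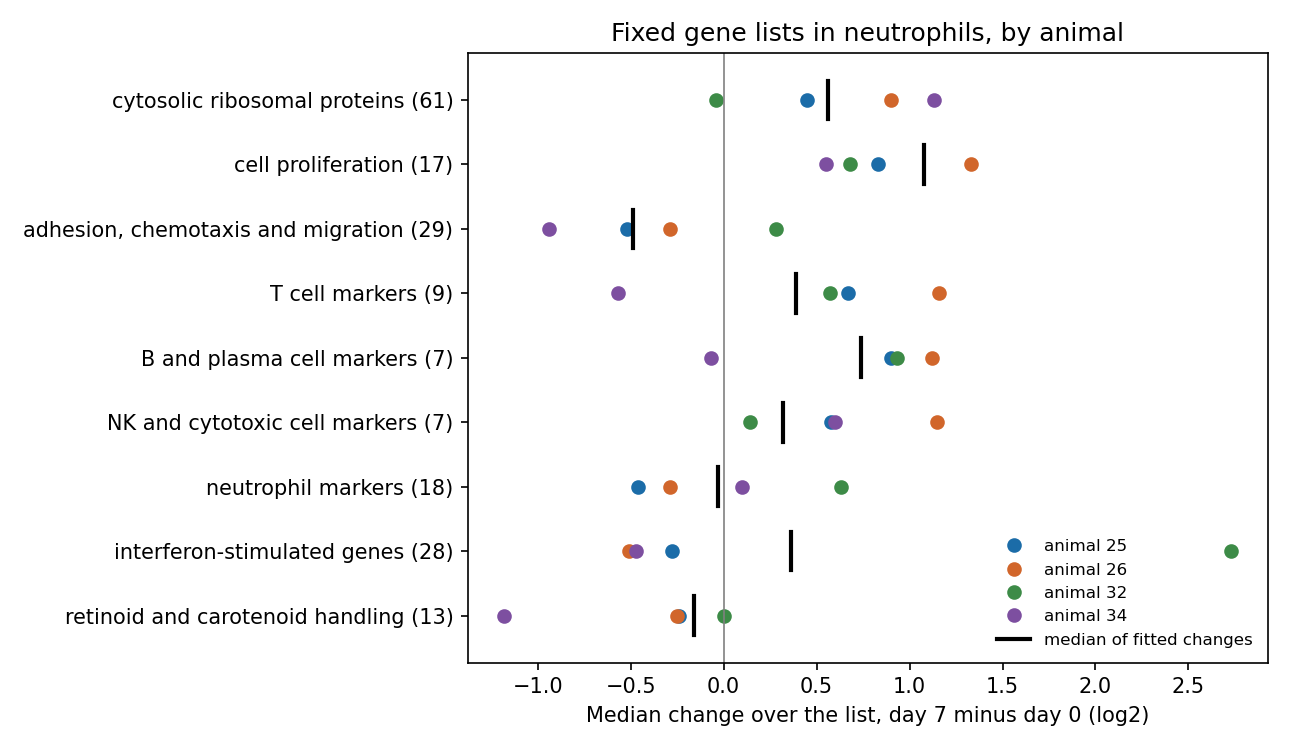
Median change from day 0 to day 7 (horizontal axis, log2) of 9 fixed gene lists in neutrophils (vertical axis, number of genes in brackets), 1 point per animal, with the bar at the median of the fitted changes. Proliferation genes were positive in all 4 animals (0.55 to 1.33), ribosomal and adhesion genes differed in sign in animal 32 (-0.04 and 0.28), and interferon-stimulated genes reached 2.73 in animal 32 against -0.51 to -0.28 in the others.

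Of the 9450 probes tested in neutrophils, 0 passed with limma (smallest adjusted p = 0.301), with 1267 at an unadjusted p under 0.05, where chance gives 472. The count was 24 in 1 fit over all 14 arrays and 1837 with array quality weights, which gave animal 25 a weight of 4.50 and animals 32 and 34 weights of 0.42 and 0.28. With the same weights and the days of animal 32 exchanged, 2533 probes passed. Named by the rule for genes that did not pass, all with the same sign in 4 of 4 animals and an adjusted p of 0.301, the positive changes with the smallest p were HS3ST1 (1.53 ± 0.23), FOCAD (1.47), NCAPG2, a condensin subunit (1.52), PCLAF, a PCNA-associated factor (1.57), JCHAIN, LOC504548, described as similar to the ubiquitin-like FAT10 (1.34), BHLHE41 (1.54), ARHGAP24 (1.34), HASPIN, a mitotic histone kinase (at least 2.42-fold), and HOMER1 (1.55). The negative changes with the smallest p were GLG1 (at least 1.15-fold), COQ8A (-1.53), AHR, the aryl hydrocarbon receptor (-1.23), DNAJC30 (-1.55), ALOX5, CCR3, INSR, the insulin receptor (-1.45), GPR4 (-1.42) and BCL2L11, the pro-apoptotic BIM (-1.23). FBL, the nucleolar methyltransferase fibrillarin, was well above background on 4 day 0 arrays and on 0 day 7 arrays, too close to the detection limit for a fold.

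The remaining 22 lists did not pass in neutrophils (adjusted p between 0.0895 and 0.996). Medians were -0.20 for the 14 genes of the NADPH oxidase and oxidative burst, -0.22 for phagocytosis and Fc or complement receptors, 0.18 for granule and antimicrobial proteins, 0.02 for apoptosis and survival and 0.13 for antioxidant and glutathione enzymes. The 13 retinoid and carotenoid genes had -0.16 (adjusted p = 0.488), with RDH5 at 0.98 ± 0.34, RXRA at -1.39 ± 0.55 and RARA at -0.79 ± 0.32 (adjusted p = 0.334, 0.358 and 0.364). The other RXRA probe had 0.12 ± 0.27 (adjusted p = 0.851). PRDX1, a peroxiredoxin, had 1.20 ± 0.27 and HSP90AB1, a cytosolic chaperone, 1.24 ± 0.23 (adjusted p = 0.301 for each). The 28 interferon-stimulated genes had a median of 0.36 (adjusted p = 0.191), made of 2.73 in animal 32 and -0.28, -0.51 and -0.47 in animals 25, 26 and 34. Their median was -0.41 without animal 32 (adjusted p = 0.0116), against 0.56, 0.71 and 0.67 without animals 25, 26 and 34 (0.0198, 0.00493 and 0.00289). The 70 oxidative phosphorylation genes had 0.17 (adjusted p = 0.0895) and passed with normexp and quantile (0.21, 0.00803), with quantile normalization of the processed signal (0.23, 0.0228) and without animal 32 (0.26, 0.00107). Granule and antimicrobial proteins passed without animal 25 (0.35, 0.02) and phagocytosis and receptor genes without animal 32 (-0.45, 0.0267). With an estimated correlation each of these calls had an adjusted p of 0.548 or more.

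Between the tissues, the day 7 minus day 0 change differed for 101 of 8841 probes measured in both (limma over all 14 arrays, 64 more positive and 37 more negative in liver). This fit takes 1 error variance per probe for both tissues, and whether that holds was not tested. Over the probes in rows 41 to 152, changes had an SD of 0.32 in liver and 0.56 in neutrophils. The cell-cycle genes CDK1 and CCNB1 differed. CDK1 had -1.27 in liver and 1.64 in neutrophils (difference -2.91 ± 0.50, adjusted p = 0.0376) and CCNB1 had -1.36 and 1.49 (difference -2.85 ± 0.47, adjusted p = 0.0328). Neither passed without the animal as a block (0.0855 for CDK1 and 0.0527 for CCNB1) or without the filter on dim probes (0.0684 and 0.0643). Neither passed without animal 58, 61, 66 or 25 (0.124 to 0.173 for CDK1 and 0.13 to 0.158 for CCNB1). With normexp and quantile normalization the differences were -1.05 (adjusted p = 0.059) and -1.34 (0.0379). The proliferation list differed as a whole (16 genes, median difference -1.20, camera, adjusted p = 1.38e-06), as did the ribosomal proteins (60 genes, -0.51, adjusted p = 1.38e-06; medians 0.06 in liver and 0.56 in neutrophils), both with an adjusted p of 0.88 with an estimated correlation. The other 17 lists did not pass (adjusted p from 0.222). The other named genes followed the liver change, MSX2 (5.33 ± 0.52, adjusted p = 0.00655), MYH7 (5.13 ± 0.59, 0.00938), LAS1L (4.92 ± 0.54, 0.00851), GBF1 (4.79 ± 0.40, 0.00566), SCP2 (4.39 ± 0.77, 0.0403), MARS1 (-4.44 ± 0.50, 0.00938), MAFG (-2.71 at its liver bound, 0.0114) and SLMAP (-2.92 ± 0.37, 0.0114), all but MYH7 in spot rows 1 to 4 or 190 to 192. With normexp and quantile normalization LAS1L had 1.42 (adjusted p = 0.168) and MAFG -1.04 (0.14), neither past the threshold, and MARS1 had -1.60 (0.0146) and SCP2 2.20 (0.0164). SCP2 also missed the threshold without the block (0.141), without the filter on dim probes (0.0689) and with quantile normalization of the processed signal (0.0526). Without single animals, SCP2 did not pass without 58, 61, 66, 25 or 26 (0.111 to 0.164), MAFG without 61, 66 or 25 (0.0677 to 0.086), SLMAP without 58, 61 or 66 (0.0653 to 0.086), MARS1 without 58 (0.0514) and MYH7 without 25 (0.0544). Of the 101 calls, 81 lie in the first or last 16 rows. With the row trend removed 6 probes passed, MYH7 (5.20, adjusted p = 0.0335) and GBF1 (3.41, 0.0363) among them. GBF1 lies in row 2, in the edge rows where liver changes still spread more after the removal. Smaller differences that did not pass were left for MSX2 (3.77, 0.0535), MARS1 (-3.77, 0.0535), LAS1L (3.53, 0.0973) and SCP2 (3.32, 0.185). The same held for MAFG (-2.63 as fitted, 0.117) and SLMAP (-2.03, 0.129). CDK1 and CCNB1, in rows 78 and 123, kept differences of -2.86 and -2.85 with the row trend removed and did not pass (adjusted p = 0.128 and 0.0973). Leaving out 1 animal at a time gave between 15 (animal 61 or 25) and 267 (animal 34) probes, with 226 without animal 32.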

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

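The tests of the spot-row trend, of gene changes as the whole source of the edge calls, of the row trend as the source of the muscle transcripts, of the signs in each animal and of the array of animal 34 were chosen after the results were seen. The other splits of the samples were not. For the additional muscle and lymphocyte transcripts, the limits were set before their values were seen, but for patterns the results had already shown.

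Liver calls lie mostly in the first and last 16 spot rows. A change of the genes as the whole source is argued against by the median over all probes tested in the first 16 rows, 0.54, which is far from 0 in each animal (0.47 to 0.61). A signal trend along the rows that differs between the day 0 and day 7 arrays may account for much of the pattern: spots of the single GAPDH sequence changed more in the first than in the last 40 rows by at least 0.88 in each liver, against an SD of 0.12 to 0.16 among inner spots. The SD was 0.61 to 0.73 among spots of the first 40 rows and 0.47 to 0.54 among those of the last 40, with the trend inside those rows included. The thresholds of both tests were set after these values were known. A treatment or day effect on particular edge genes stays open and untested.

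Skeletal muscle transcripts were higher in all 3 livers on day 7. The row trend is argued against, since the raised members of the list had a median change of 5.33 with the trend removed and the 4 members without a day 0 level at their bounds (2.78 for MYH1 to 7.82 for ACTA1). Muscle tissue in the day 7 samples stays open. Of 16 muscle transcripts tested outside the list, 25% (SLN, MYH7, ATP2A1 and PGAM2) rose by over 1 in every animal. This lies between the bounds set for and against it. MYH7 was already among the muscle genes named above. TNNC2 and TNNC1, named above and also outside the list, were not among the 16 and were higher on day 7 in every animal. Some of the 16 were bright in liver on day 0, such as CA3 (mean log2 signal 3.56) and HSPB6 (-0.43). A small share of muscle would raise these little, so the 25% cannot decide. Of the 16, 14 were positive with a median of 0.84 (camera at the preset correlation, p = 9.48e-10). TCAP and TPM2, dimmer on day 0 (-3.66 and -5.75), had -0.10 and -0.01. A change of expression within liver cells also stays open and was not tested.

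Ribosomal and proliferation genes were higher in neutrophil samples on day 7. The weak array of animal 34 as the source is argued against, because without that animal both lists passed camera at the preset correlation with adjusted p of at most 6.6e-06. With an estimated correlation neither list passed over all 4 animals (adjusted p = 0.777 for each). Lymphocytes in the day 7 preparations may contribute. A set of 10 transcripts of lymphocytes outside the fixed lists had a median of 0.59 (camera p = 0.000492, and 0.0529 with an estimated correlation). Among them were GIMAP4 (1.11) and TXK (1.01), with SPIB (0.06 ± 0.64) and UBASH3A (0.03 ± 0.41) near 0. Not all 10 are particular to lymphocytes. IL2RA (2.67), GIMAP4 (2.35), CD69 (2.02), PTPRCAP (1.52) and XBP1 (1.25) had mean day 0 signals above those of the T cell list (-1.37 to -0.66). Signals of different probes compare only roughly, so the changes of these transcripts may, but need not, come from other cells. For the ribosomal genes this stays open, since ribosomal, T cell and B cell medians had the same sign in 2 of 4 animals, with -0.04, 0.57 and 0.93 in animal 32 and 1.13, -0.57 and -0.07 in animal 34, while the 10 transcripts had 0.49, 0.80, 1.22 and 0.75 in animals 25, 26, 32 and 34. A change within neutrophils after the treatment stays open and untested.

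Other splits were counted that exchange the days within animals. The 435 liver probes were reached by 1 of 4 splits (highest other 0) and the 7 liver lists by 2 of 4 (highest other 10). The 0 neutrophil probes were reached by 8 of 8 (highest other 0) and the 3 neutrophil lists by 7 of 8 (highest other 10). These splits are too few for a share under 0.05, and no split could give fewer than 0 neutrophil probes. Splits with exchanged days gave 5 to 10 lists in liver and 2 to 10 in neutrophils. The number of lists called, 7 and 3, therefore does not set the true days apart. With array weights, exchanging the days of animal 32 gave 2533 neutrophil probes, of animal 34 gave 364 and of animal 26 gave 0, against 1837 for the true days. The weights were 4.50 and 1.92 for animals 25 and 26 and 0.42 and 0.28 for animals 32 and 34. The weighted fit thus rests mostly on animals 25 and 26. The cause of these counts was not tested. For the 101 probes that differed between tissues, 1 of 35 divisions of the animals gave as many (highest other 0), a share under 0.05. This makes a chance division of the animals unlikely but does not exclude it. It says nothing about the slide, which differs with the tissue. Of the 101 calls, 81 lie in the first or last 16 rows, and 6 probes passed with the row trend removed.

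Of 94 groups of 4 arrays examined, 8 held a sample far from the others, where chance gives about 1 in 20. Animal 26 on day 0 had the lowest median signal, 109.2 (nearest 133.2), the lowest mean of the ribosomal list, 3.11 (3.41), and the lowest LOC504548, -2.51 (-1.04), and on day 7 an antioxidant list mean of 0.65 (0.57). Animal 32 had a neutrophil marker mean of 1.45 (1.70) on day 0 and an interferon-stimulated gene mean of 5.21 (1.90) on day 7. Animal 34 on day 7 had PCLAF at -1.42 (-2.82) and GPR4 at -3.21 (-1.51).

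The day change differed between liver and neutrophils, by a test of the difference itself, for MSX2 (5.33), MYH7 (5.13), LAS1L (4.92), GBF1 (4.79) and SCP2 (4.39). It also differed for MARS1 (-4.44), MAFG (-3.40 as fitted), SLMAP (-2.92), CDK1 (-2.91) and CCNB1 (-2.85). MAFG had -2.71 at the bound of its day 7 level in liver, which was not well above background. Of these genes, MYH7 and GBF1, the latter in spot row 2, passed with the row trend removed and the others did not. The proliferation (median -1.20) and ribosomal (-0.51) lists differed with camera's preset correlation. With an estimated correlation both had an adjusted p of 0.88.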

How the results depend on the processing

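Removal of the row trend and the restriction to inner rows were chosen after seeing the data. With the row trend removed GAPDH turned from 1.13 to -0.41 and ENG from 0.88 to -0.34. No other count, list or gene given here from the sets of named and called genes reversed under the alternatives run. Some lists that had not passed did change sign. The interferon-stimulated list of neutrophils turned from 0.36 to -0.41 without animal 32. In the inner rows, neutrophil medians turned from 0.13 to -0.08 for antioxidant, from -0.16 to 0.06 for retinoid and from 0.02 to -0.30 for apoptosis genes. The 435 liver probes became 210 without the animal as a block, 0 without the filter on dim probes, 22 with the row trend removed, 0 in the inner rows, 177 in 1 fit over all arrays, 790 at an adjusted p of 0.1, 962 at an unadjusted p with 1.5-fold, and 0 to 159 with an animal left out (0 without 58, 116 without 61, 159 without 66). The 0 neutrophil probes became 24 in 1 fit over all arrays, 1253 at an unadjusted p with 1.5-fold and 1837 with array weights, and stayed at 0 without the block and with any animal left out. The 101 probes that differed between tissues became 66 without the filter, 6 with the row trend removed, 0 in the inner rows and 15 to 267 with an animal left out (76 without the block). The 7 liver lists became 3 with normexp and quantile, 3 with quantile normalization, 3 with probes above background on every array, 13 with the row trend removed, 11 in the inner rows, and 0 with an estimated correlation and 0 with fry (6 without the block). The 3 neutrophil lists became 6 with normexp and quantile, 5 with probes above background on every array, 4 to 7 with an animal left out, and 0 with an estimated correlation and 0 with fry (3 without the block). The cause was not tested, except that fewer arrays or probes were used where animals or rows were left out and that fewer probes had small p-values without the row trend. Of the values of single genes and lists under the alternatives, 327 of the liver genes, 63 of the liver lists, 235 of the neutrophil genes, 39 of the neutrophil lists and 95 of the gene differences kept their direction and side of the threshold; 255, 34, 0, 6 and 42 no longer passed and 29 of the neutrophil genes newly passed. Signal over background limits dim genes, most in the day 7 neutrophil array of animal 34, with 57.1% of spots well above background.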

Other observations

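Among antioxidant genes in liver, GCLM, a subunit of the rate-limiting enzyme of glutathione synthesis (1.59 ± 0.17, limma adjusted p = 0.0217), and NFE2L2, the transcription factor NRF2 (1.28 ± 0.14, 0.0226), rose, and PRDX2, a peroxiredoxin (-1.24 ± 0.16, 0.0342), fell, in spot rows 4, 5 and 190. With the row trend removed they had 0.50, 0.32 and -0.50 and none passed (adjusted p = 0.389, 0.483 and 0.307). CISH, a STAT5 target that dampens cytokine signalling (1.54, 0.0352, row 4), AKR1C4 (0.92, 0.0198, row 18) and the class II gene BOLA-DQA1 (1.01, 0.0446, row 51) rose and SHMT1, a serine hydroxymethyltransferase (-1.43, 0.0289, row 183), fell. None of these 4 passed with the row trend removed. CISH then had 0.45 (adjusted p = 0.483), whereas AKR1C4 had 0.68 (0.113), BOLA-DQA1 0.95 (0.129) and SHMT1 -1.22 (0.138).

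In neutrophils the interferon-stimulated genes of animal 32 stood apart from those of the other animals. CXCL10, an interferon-induced chemokine, had 7.18 in animal 32 and 0.05, 0.26 and 0.56 in animals 25, 26 and 34, and GBP4, an interferon-induced GTPase, had 5.39 against 0.40, 0.88 and 0.85. Over all 4 animals neither passed (limma adjusted p = 0.453 and 0.373). The beta-defensin LAP had 1.06 ± 0.26, positive in 4 of 4 animals (adjusted p = 0.303), and CYBB, the catalytic subunit of the phagocyte NADPH oxidase, had -0.51 ± 0.43, with 0.92 in animal 32 and -0.67, -0.52 and -1.76 in animals 25, 26 and 34 (adjusted p = 0.588).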
